A study of Mus musculus with 14 samples.

How the data were processed

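Polyadenylated RNA from the heart ventricles of 14 male mice was sequenced as paired-end libraries, 4 hours after an intraperitoneal injection of vehicle (DMSO) or of MRL5, a compound of the GX family known only by its code name. Per the labels, the mice were wild type (WT) or carried the GX change of a cardiac sodium channel on both alleles, and MRL5 blocks the changed channel. The groups held 4 GX mice with DMSO, 5 GX mice with MRL5, 3 WT mice with DMSO and 2 WT mice with MRL5, and each library came from a separate mouse per the labels. The design text gives 4 GX mice with MRL5, while the labels give 5, and all 5 were used. Replicate numbers follow the order of the records and pair no mice.

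The deposited table holds 1 value per gene and library in a signal unit that its header names scaled reads per base. Per the submitters' processing notes, reads were quantified with kallisto and compared with sleuth 0.3.0 on mouse build GRCm38, and the annotation release is not given in the sources used here. The deposited signal values are not counts: by the name of the unit they are reads per base that were then scaled. How they were scaled is not known here, so they may not remain divided by transcript length. The authors also deposited p-values and q-values of MRL5 against DMSO in each genotype, with effects on a natural log scale, and a column marking 86 cardiac conduction genes. Genes in the deposited table are those that the authors' filter kept, and how reads of overlapping or near-identical genes were divided is not given in the sources used here.

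Of the 14307 entries in the table, 146 had values identical to another entry and were left out, and 22 symbols that a spreadsheet had turned into dates were restored. Positions are those of the GENCODE M21 annotation of GRCm38, which holds 14117 of the 14161 genes. Values were not rescaled. A gene was tested when its value was at least 1 in at least 2 of the 14 libraries. Tests ran on log2(value + 1), so the fold changes of genes with low values are understated. The design fixed in advance named a count test first and limma as the fallback for a unit that is not counts, and the fallback was used. A transcript-level test was not run, because the table is per gene.

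The main test was limma 3.58.1 in R 4.3.3, with trend and robust variance estimates, 1 mean per group and no covariate, over all 14 libraries with 10 residual degrees of freedom. The contrasts read from it were MRL5 against DMSO in each genotype, GX against WT under each treatment, and the difference between the effects of the compound (the interaction). Benjamini-Hochberg adjusted p-values under 0.05 were called. Standard errors (SE) are limma's moderated values. All tests were two-sided. Gene lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 over 34 lists, with camera at an estimated correlation and fry beside it. List means were also compared by exact permutation in Python 3.11.15 with scipy 1.17.1.

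Genes named in the text followed a rule fixed before the data were examined: called genes whose groups do not overlap, or, where fewer than 5 passed, the 5 with the smallest p, skipping predicted genes. Added to these were the 4 members with the smallest p of each list that passed, and the sodium channel genes. Results of some single genes are not reported here. Genes outside the rule are marked as chosen after their values were seen, or are named for their q in the authors' deposited table.

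The tests were tried on simulated data built from the real means and residual spreads. Each gene was drawn independently, without library sets, an alike pair, an outlying library or correlation between genes. The shares recovered may therefore be too high for the real libraries. With 100 genes changed by 1 on the log2 scale in MRL5 against DMSO of GX mice, 79 were recovered, and 90 of 100 genes changed by 2. In the same order, 59 and 82 were recovered for MRL5 against DMSO of WT mice, 71 and 91 for GX against WT under DMSO, and 68 and 80 for GX against WT under MRL5.

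Among values under 30, between 23.1% and 26.9% per library came out whole within 0.05 reads at the best-fitting step, against 10% by chance for a step not fitted to them. No value of 1 read or depth was taken from this, and no interval from counts is given.

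The library names give a technical grouping: 1 set numbered 174 holds GX MRL5 4, WT DMSO 2 and WT DMSO 3, and the set numbered 148 holds the other libraries, 4 of them with an index of 0. Alternatives were other scalings (equal column sums, median ratios), other filters, a pseudocount of 0.1, an added threshold of 1 on the log2 fold change, only the groups compared, the library set or the set with index series as a covariate, only set 148, and each library left out in turn. Alternatives added after seeing the data were leaving out both of the most alike libraries, an index of short against long transcripts as a covariate, list counts under several of these settings, and the permutation of list means. The index was the median deviation from the all-library mean in the fifth of genes with the shortest transcripts, minus that in the fifth with the longest, over 9851 genes with a mean value above 50.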

Results

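Expression of 14156 genes was measured in ventricles of GX and WT mice. Column sums of the deposited signal lay between 17244042 and 22163644, and mitochondrial genes held between 38.9% and 49.7% of them. Pairwise correlations between libraries over 10915 genes ran from 0.958 to 0.992, with a median of 0.981 within groups and 0.980 between groups. The first principal component held 18.5% of the variance.

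None of the 16 tested genes of the sodium channel list passed in any of the 5 contrasts with limma, also when adjusted over the list alone.

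The first comparison asks what MRL5 changes in ventricles that carry the sensitive channel. Inflammatory genes were the group with the largest shift: 20 of 21 tested members had a positive fold change, with a median of 1.14 on the log2 scale (camera adjusted p = 1.46e-13). The list was not called with an estimated correlation (adjusted p = 0.432). Lcn2, an iron-binding acute phase protein (chromosome 2, 32384633 to 32388252), had a mean of 217 ± 108 (SD, n = 5) with MRL5 and 54.3 ± 14.1 (SD, n = 4) with DMSO, a log2 fold change of 1.87 (SE 0.341). Ccl2, a chemokine that attracts monocytes, had a log2 fold change of 2.53 (SE 0.808), Timp1, an inhibitor of matrix proteases, 1.83 (SE 0.571) and Il4ra, a cytokine receptor chain, 0.70 (SE 0.23), which was 0.47 without GX MRL5 3. Adjusted over the list alone, these 4 genes rose and none fell. Over all genes, 0 of 14156 passed with limma (smallest adjusted p = 0.974). An unadjusted p under 0.05 was found for 585 genes (4.13%, against 5% by chance), 384 of them higher with MRL5.

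The shift was unequal between mice. The list mean per library was 8.42 in GX MRL5 3, 7.06 in GX MRL5 4, 6.46 in GX MRL5 2 and 6.28 in GX MRL5 5, and 5.63 in GX MRL5 1, which lay within the DMSO range of 5.49 to 5.82. An exact permutation test of these means gave p = 0.0635 (n = 5 and 4, smallest possible 0.0159). Without GX MRL5 3 the median was 0.51 and the list still passed camera. Within library set 148 the median was 0.99, and the exact permutation p of the list means was 0.114 (n = 4 and 4).

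**Figure D1:**
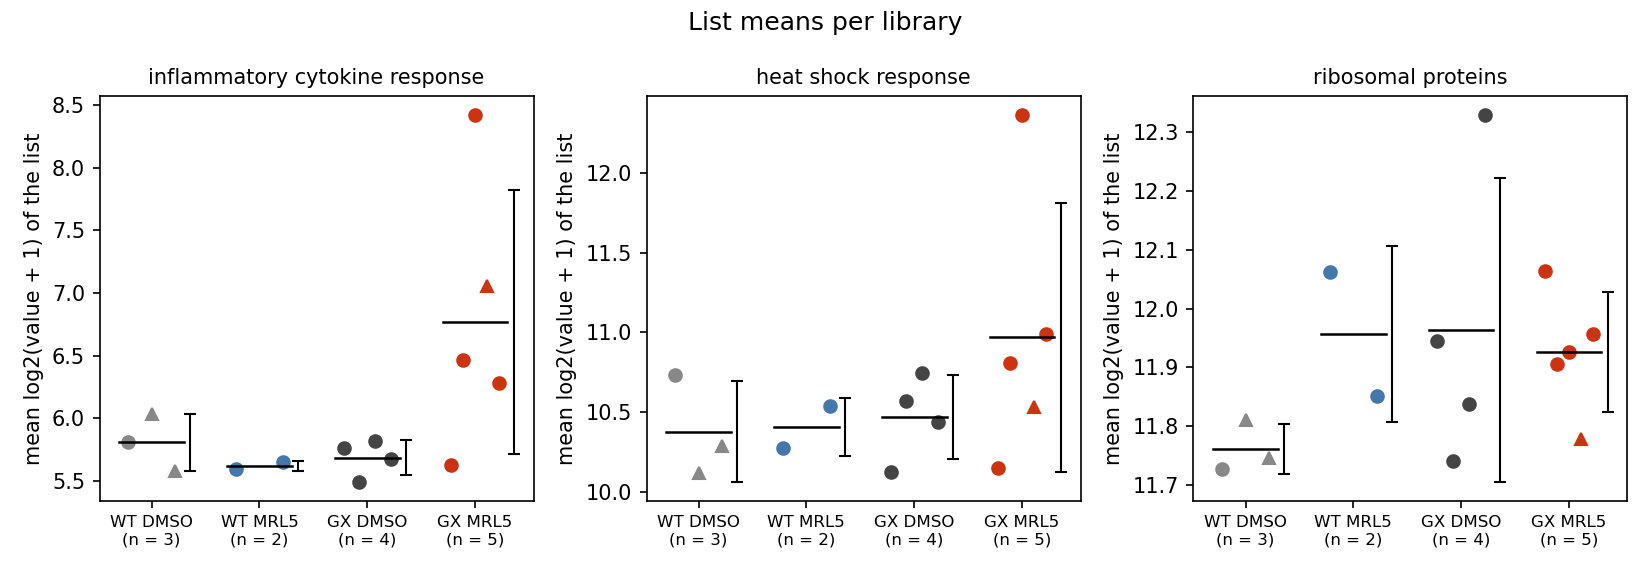
Mean log2(value + 1) of 3 gene lists per library (vertical axes) in the 4 groups (horizontal axes). Circles are libraries of set 148 and triangles of set 174, horizontal lines are group means and bars beside them 1 SD. GX MRL5 3 lies highest for inflammatory genes at 8.42, and GX DMSO 4 highest for ribosomal proteins.

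6 other lists had a higher median in GX mice with MRL5 and passed camera. Erythroid genes had a median of 0.47 (adjusted p = 0.000855, and adjusted p = 0.573 with an estimated correlation), with globin Hbb-bs at 0.46 (SE 0.187). Immediate early genes, transcribed within minutes of stimulation, had a median of 0.36 (adjusted p = 0.00169, estimated correlation adjusted p = 0.719), with Atf3 at 2.20 (SE 0.909) and Ccn2 at 0.99 (SE 0.389). Extracellular matrix genes had a median of 0.26 (adjusted p = 0.00141, estimated correlation adjusted p = 0.700), with Thbs1 at 2.29 (SE 0.919) and Lox, which cross-links collagen, at 0.63 (SE 0.234). Fetal and hypertrophy genes had a median of 0.21 (adjusted p = 0.00184, estimated correlation adjusted p = 0.573), with Rcan1, an inhibitor of calcineurin, at 12854 in GX MRL5 3 and 1409 to 3911 in the other GX MRL5 libraries, against 1270 to 1869 in GX DMSO. Heat shock genes had a median of 0.20 (adjusted p = 0.00375, estimated correlation adjusted p = 0.719). Intercalated disc genes had one of 0.05 (adjusted p = 0.027, estimated correlation adjusted p = 0.432), with Nrap at 0.40 (SE 0.182).

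GX MRL5 3 had the highest Hspa1a, at 53385 against 149 to 1187 in the other libraries, and Atf3 at 6805. Without it the heat shock median was 0.04 (adjusted p = 0.417) and the immediate early median 0.01 (adjusted p = 0.507), and the log2 fold changes were 1.36 for Atf3, 0.65 for Ccn2, 0.74 for Rcan1 and 0.24 for Nrap. The heat shock call was also lost without GX DMSO 1 (median 0.15), and the matrix call without GX MRL5 4 (median 0.12, adjusted p = 0.0755), the only library of set 174 in this contrast. The matrix call was lost within set 148 as well (0.12, adjusted p = 0.0697), and its median was 0.14 with the set as a covariate (adjusted p = 0.0184), so the set and this library cannot be told apart. Without GX DMSO 4 the immediate early call was lost while its median rose to 0.41 (adjusted p = 0.0628). The intercalated disc call was lost at a median of 0.04 without GX DMSO 4 or GX MRL5 5, and its median was 0.07 without GX DMSO 1, 0.08 without GX DMSO 3 or GX MRL5 4 and 0.09 without GX MRL5 1. The matrix median was 0.14 without GX DMSO 1 and 0.45 without GX MRL5 1, and the fetal median 0.13 without GX MRL5 3 and 0.33 without GX MRL5 5.

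Genes with the smallest p in this contrast were Lcn2, Syt12, Nsd2, Bmp4 and Flvcr2, none of which passed. Syt12 had a log2 fold change of 1.52 (SE 0.308), Nsd2, a histone methyltransferase, 0.59 (SE 0.125), Bmp4, a growth factor, 0.89 (SE 0.187) and Flvcr2, a membrane transporter, 1.22 (SE 0.263). For Lcn2, Syt12, Bmp4 and Flvcr2 each GX MRL5 library lay above each GX DMSO library. Such a gap, in either direction, was seen for 156 genes, 1.10% of those tested against 1.59% by chance. Of the glucocorticoid list, 4 genes rose and 1 fell when adjusted over the list alone. Without GX DMSO 1, limma called 2 genes: Fkbp5, a target of the glucocorticoid receptor, at 0.92 (SE 0.114, adjusted p = 0.0223) and Flvcr2 at 1.52 (SE 0.215, adjusted p = 0.0487). In the authors' deposited table, Lcn2 (q = 0.0601), Bmp4 (q = 0.0757) and Tnfrsf1a (q = 0.0757) had a q under 0.1 in GX mice and 0 genes one under 0.05.

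**Figure D2:**
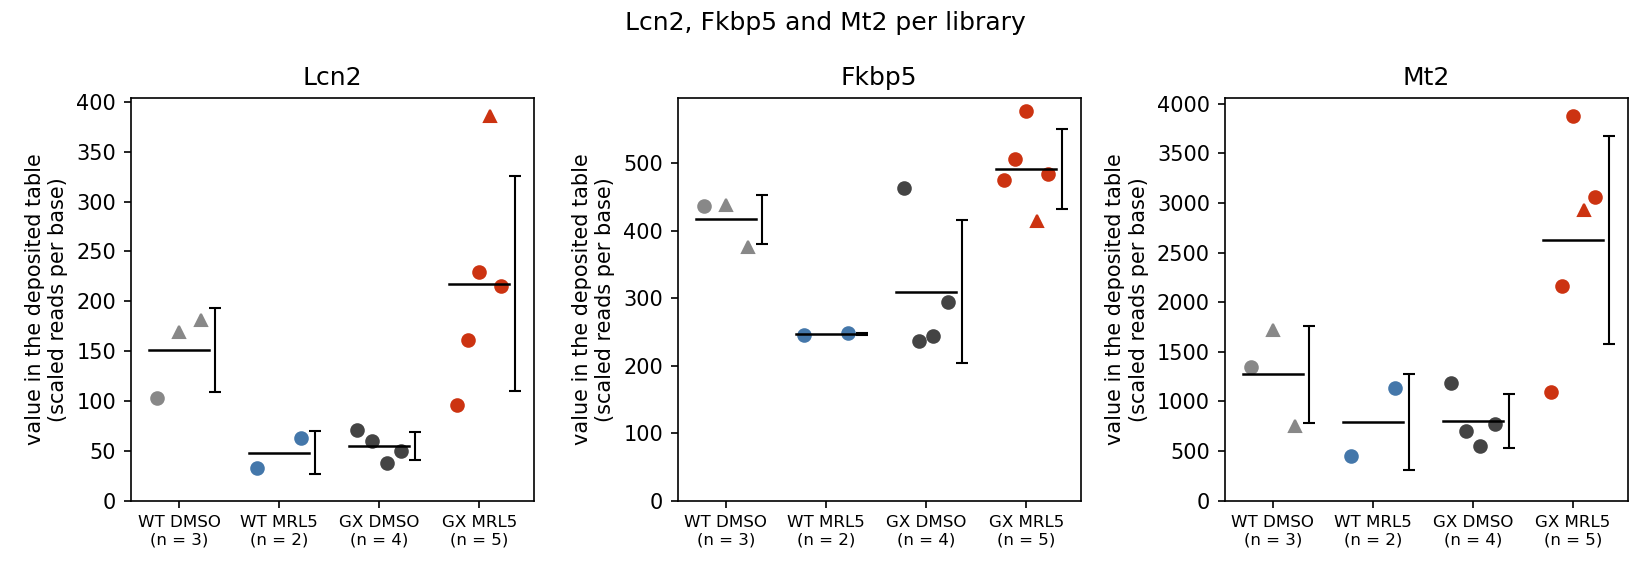
Deposited values of Lcn2, Fkbp5 and Mt2 per library (vertical axes, scaled reads per base) in the 4 groups (horizontal axes). Circles are libraries of set 148 and triangles of set 174, lines are group means and bars 1 SD. Fkbp5 was 463 in GX DMSO 1 and between 237 and 294 in the other GX DMSO libraries.

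The second comparison asks what MRL5 changes where the channel is wild type. Ribosomal protein genes had a positive fold change for 23 of 25 members (median 0.15, camera adjusted p = 0.00137, estimated correlation adjusted p = 0.998), among them Rps2 at 0.35 (SE 0.155). Oxidative phosphorylation genes were positive for 20 of 25 (median 0.16, adjusted p = 0.00294, estimated correlation adjusted p = 0.998), with Cox4i1 at 0.51 (SE 0.212) and Ndufb8 at 0.41 (SE 0.175). The inflammatory list had a median of -0.06 and did not pass (adjusted p = 0.604). Genes with the smallest p were the interferon-inducible Ifi205 (log2 fold change -0.90, SE 0.175), Zc3h6 (1.16, SE 0.249), Ppp1r9a (-0.77, SE 0.173), Nsd2 (-0.73, SE 0.169) and the lysosomal fucosidase Fuca1 (0.62, SE 0.145).

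With limma 0 of 14156 genes passed (smallest adjusted p = 0.831), and 799 (5.64%) had an unadjusted p under 0.05. By the authors' deposited table, a total of 5 genes had a q under 0.05 in WT mice: Hmox1 (q = 4.42e-05), Rrad (q = 0.000139), Amd1 (q = 0.000813), Ifi205 (q = 0.000813) and Fkbp5 (q = 0.00723). In the same order, their limma log2 fold changes were -0.99, 0.83, -0.64, -0.90 and -0.75, each with a limma adjusted p = 0.831. WT MRL5 held only 2 libraries: without WT MRL5 2 limma called 58 genes and without WT MRL5 1 it called 0, and the lone library is then assumed to vary like the other groups. The ribosomal call was lost without WT MRL5 1 (median 0.09, adjusted p = 0.0839), and its median was -0.0085 (adjusted p = 0.907) with the short-transcript index as a covariate. The oxidative phosphorylation call was lost without WT DMSO 2 (median 0.07), within library set 148 (0.03, adjusted p = 0.892, with only 1 WT DMSO library), with the library set as a covariate (0.05, adjusted p = 0.69) and with the index (0.04, adjusted p = 0.33). Without WT MRL5 2 its median was higher, at 0.21, but did not pass (adjusted p = 0.0539). Without WT MRL5 1 the fold changes in WT mice were 0.17 for Rps2, 0.24 for Cox4i1, 0.23 for Ndufb8 and 0.75 for Zc3h6, and without WT MRL5 2 that of Cox4i1 was 0.78.

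The third comparison sets GX against WT under vehicle. Ribosomal protein genes had positive fold changes for 23 of 25 members (median 0.20, camera adjusted p = 1.59e-06), with Rps20 at 0.42 (SE 0.153). With an estimated correlation neither this list nor any other named in this paragraph passed (smallest adjusted p = 0.616). Oxidative phosphorylation (median 0.11), endothelial (0.16), glucocorticoid (0.21) and immediate early genes (0.21) also passed with higher values in GX, with Tie1, an endothelial receptor, at 0.35 (SE 0.111), the kinase Sgk1 at 0.53 (SE 0.176) and Klf4 at 0.37 (SE 0.142). Not all glucocorticoid genes went the way of Sgk1. Fkbp5 was at 463 in GX DMSO 1 and 237 to 294 in the other GX DMSO libraries, against 375 to 439 in WT DMSO. Mt2 was at 546 to 1183 in GX DMSO and 751 to 1722 in WT DMSO. For this contrast both were chosen after their values were seen. Conduction system genes (median -0.34, adjusted p = 0.0354), circadian clock genes (-0.17) and erythroid genes (-0.39) passed with lower values, with the pacemaker channel Hcn4 at -0.65 (SE 0.247) and Hlf at -0.26 (SE 0.115). Genes with the smallest p were Aff3 (log2 fold change -1.26, SE 0.258), Ints4 (0.62, SE 0.13), Fbxl22 (0.53, SE 0.112), Fam126a (-0.49, SE 0.106) and Ntn3 (-1.42, SE 0.32).

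With limma 0 of 14156 genes passed (smallest adjusted p = 0.866), and 802 (5.67%) had an unadjusted p under 0.05. The atrial light chain Myl7 was at 3967 in WT DMSO 2, 643 in GX DMSO 3 and 133 in GX MRL5 4. It was at most 20.7 in each other library, and the atrial light chains were chosen after their values were seen. WT DMSO 2 and GX DMSO 3 also had the highest conduction list means, at 7.68 and 7.34. The other libraries lay between 5.39 and 6.74. Hcn4 was at 441 in WT DMSO 2 and 314 in GX DMSO 3. It was also at 357 in WT DMSO 3 and 382 in WT MRL5 2, where Myl7 was at 6.90 and 11.6. Myl4, the other atrial light chain, was at 53.7 and 103 there, against 32.5 in WT DMSO 1. GX MRL5 4, with Myl7 at 133, had a conduction mean of 6.25. Conduction genes and Myl7 thus did not rise together in each library. Whether the atrial signal of WT DMSO 2 accounts for the conduction difference between genotypes can therefore not be decided. Library set is in part confounded with genotype here, since set 148 holds all GX DMSO libraries and only 1 of WT DMSO. With the set as a covariate the calls were lost for oxidative phosphorylation (median 0.00707, adjusted p = 0.91), endothelial (0.07, adjusted p = 0.147), glucocorticoid (-0.10, adjusted p = 0.433), immediate early (0.000902, adjusted p = 0.737), conduction (-0.27, adjusted p = 0.661) and erythroid genes (-0.33, adjusted p = 0.0609). Within set 148 the conduction median was -0.03, the endothelial one -0.03 and the oxidative phosphorylation one -0.0013, and 1 list passed in place of 8, but there WT DMSO is a lone library whose spread is taken from the other groups. The ribosomal median fell to 0.07 without GX DMSO 4 (adjusted p = 0.0258), and Rps20 to 0.27. With the short-transcript index as a covariate the calls were lost for ribosomal (median 0.04, adjusted p = 0.128), oxidative phosphorylation (0.04, adjusted p = 0.204), circadian (-0.16, adjusted p = 0.0869), conduction (-0.24, adjusted p = 0.0869), erythroid (-0.28, adjusted p = 0.117) and glucocorticoid genes (0.11, adjusted p = 0.128). In that setting 5 lists passed, 4 with higher values in GX and 1 with lower values. With equal column sums the conduction (-0.43, adjusted p = 0.17) and circadian calls (-0.25, adjusted p = 0.068) were lost although their medians were farther below 0. This scaling moved the median of all genes from -0.02 to -0.11, and list medians move down with it, also those above 0. With it 5 lists passed with higher values in GX and 1 with lower values.

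The other 7 list calls of this contrast were each lost without any 1 of several libraries. Conduction genes lost theirs without WT DMSO 2 (median -0.16, adjusted p = 0.761), GX DMSO 2 (-0.16) or GX DMSO 1 (-0.27), and had -0.64 without GX DMSO 3 and -0.63 without WT DMSO 1. Erythroid genes lost theirs without WT DMSO 2 (-0.14), GX DMSO 1 (-0.28) or GX DMSO 3 (-0.39), and had -0.63 without WT DMSO 3. For circadian genes these were GX DMSO 2 (-0.14), GX DMSO 4 (-0.12) and WT DMSO 3 (-0.13), and for oxidative phosphorylation WT DMSO 2 (0.04) and GX DMSO 4 (0.08), with 0.20 without GX DMSO 3 and 0.21 without WT DMSO 1. Endothelial genes lost theirs without WT DMSO 3 (0.09) or GX DMSO 3 (0.17), and had 0.27 without WT DMSO 1 and 0.10 without WT DMSO 2. Glucocorticoid genes lost theirs without GX DMSO 1 (0.08) or WT DMSO 3 (0.13), with 0.33 without GX DMSO 2, and immediate early genes without GX DMSO 1 (0.18), GX DMSO 2 (0.16), GX DMSO 3 (0.14) or WT DMSO 3 (0.13).

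**Figure D3:**
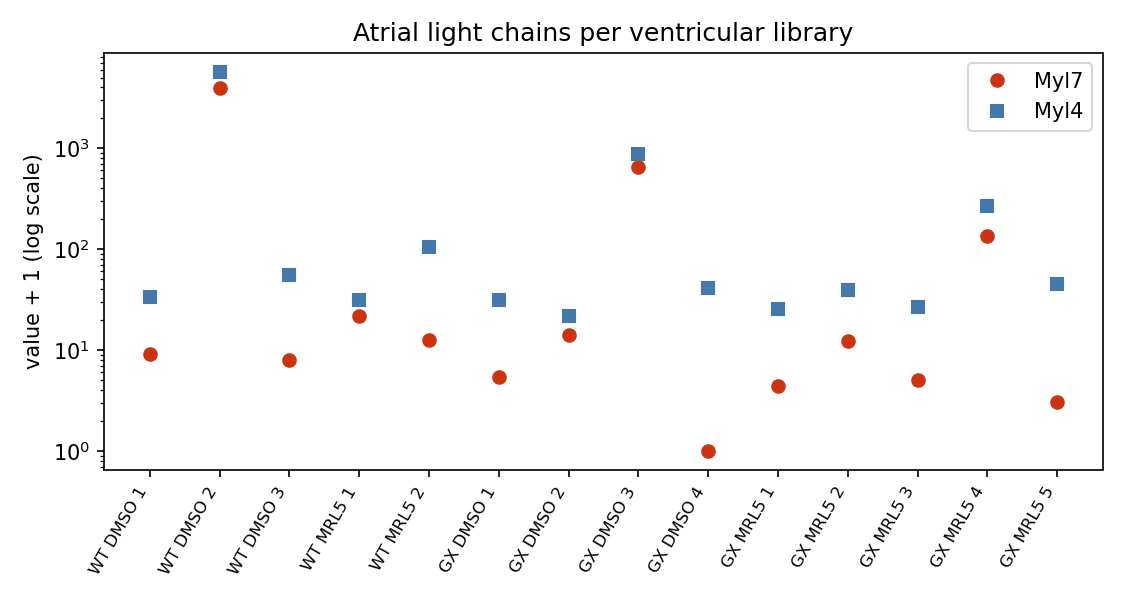
Deposited values plus 1 of the atrial light chains Myl7 and Myl4 (vertical axis, log scale) in each of the 14 ventricular libraries (horizontal axis). Points are single libraries. WT DMSO 2 has Myl7 at 3967 and Myl4 at 5676, before adding 1.

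Under MRL5, GX mice had higher values than WT mice for inflammatory genes (median 1.01, 20 of 21 positive, camera adjusted p = 3.77e-10) and glucocorticoid response genes (median 0.41, 16 of 19 positive, adjusted p = 4.52e-07). With an estimated correlation neither these lists nor the others named here passed (smallest adjusted p = 0.636). Fkbp5 differed by 0.98 (SE 0.205), the metallothionein Mt2 by 1.75 (SE 0.49), Lcn2 by 2.09 (SE 0.426) and Osmr, a receptor for oncostatin M, by 1.01 (SE 0.256). Adjusted over the list alone, 7 glucocorticoid and 5 inflammatory genes were higher and none lower. Immediate early (median 0.52), fetal (0.42) and matrix genes (0.44) passed with higher values and interferon response genes (-0.15) with lower values. Genes with the smallest p were Ifi205 (1.02, SE 0.161), Nsd2 (0.83, SE 0.155), Syn2 (1.10, SE 0.21), Wdhd1 (-2.01, SE 0.392) and Zc3h6 (-1.12, SE 0.228).

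With limma 0 of 14156 genes passed (smallest adjusted p = 0.226), and 932 (6.58%) had an unadjusted p under 0.05. Without WT MRL5 2 limma called 63 genes, and without WT MRL5 1 it called 0. The interferon median was 0.12 without WT MRL5 1 and -0.04 without GX MRL5 1, neither called, and -0.53 without WT MRL5 2. The matrix call was lost without WT MRL5 1 (median 0.17), without GX MRL5 4 (0.27) and within set 148 (0.27, adjusted p = 0.054). The fetal median was 0.07 without WT MRL5 2 (adjusted p = 0.46) and 0.84 without WT MRL5 1, where Mt2 was at 1.09 and Zc3h6 at -0.72. Without GX MRL5 3 the inflammatory median was 0.52 (adjusted p = 5.17e-09) and the immediate early median 0.16 (adjusted p = 0.00214), and without GX MRL5 1 the inflammatory median was 1.59.

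The difference between the effects of MRL5 in GX and in WT mice was tested as an interaction. It was positive for 19 of 21 inflammatory genes (median 1.27, camera adjusted p = 2.77e-05), for erythroid genes (0.64) and for circadian clock genes (0.20), and negative for ribosomal protein (-0.25), oxidative phosphorylation (-0.22) and glycolysis genes (-0.16). With an estimated correlation none of these lists passed (smallest adjusted p = 0.524). Lcn2 had a value of 3.54 (SE 0.577), Nsd2 1.32 (SE 0.21), Ifi205 1.19 (SE 0.218), Fkbp5 1.46 (SE 0.277) and Ppp1r9a 0.98 (SE 0.214). Part of the Lcn2 and Fkbp5 values came from a fall in WT mice. Lcn2 was at 103 to 181 in WT DMSO, 32.7 and 63.2 in WT MRL5, and 95.8 to 386 in GX MRL5. Fkbp5 had a log2 fold change of -0.75 (SE 0.223) in WT mice. It was at 375 to 439 in WT DMSO and 414 to 578 in GX MRL5, so these 2 groups overlapped for both genes. Adjusted over the list alone, 1 inflammatory gene (Lcn2) and 2 glucocorticoid genes passed.

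With limma 0 of 14156 genes passed the interaction test (smallest adjusted p = 0.185), and 904 (6.39%) had an unadjusted p under 0.05. Without both of the most alike libraries, Fkbp5 (1.68, SE 0.191, adjusted p = 0.0149) and Lcn2 (3.94, SE 0.487, adjusted p = 0.0201) were called, and without WT MRL5 2 there were 27 called genes. Of the list calls, the inflammatory one held with each library left out (median 0.83 without GX MRL5 3) and with the short-transcript index as a covariate (0.77). The ribosomal call was lost without GX DMSO 4 (-0.05, adjusted p = 0.16), with the set as a covariate (-0.10, adjusted p = 0.06) and with the index (-0.0014, adjusted p = 0.908), and its median was -0.14 without WT MRL5 1. The oxidative phosphorylation call was lost without WT DMSO 2 (-0.13), with the set (-0.05, adjusted p = 0.791), within set 148 (-0.06) and with the index (-0.06, adjusted p = 0.211), and its median was -0.12 without GX DMSO 4. The glycolysis median turned to 0.00563 with the set and to 0.03 within set 148, and its call was also lost without WT DMSO 2 (-0.07), GX DMSO 4 (-0.10) or WT MRL5 2 (-0.17) and with the index (-0.07), while it was -0.27 without WT DMSO 1. The circadian call was lost without GX DMSO 4 (0.17), WT DMSO 2 (0.17) or WT MRL5 2 (0.19) and within set 148 (0.20, adjusted p = 0.0572), and the erythroid call without WT DMSO 2 (0.41) or WT MRL5 2 (0.73). Across genes, which are not independent replicates, the compound effects in GX and in WT mice correlated at r = -0.119, with no library shared between them.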

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

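Tests on the most alike pair, on 1 library, on the library set, on macrophages and on transcript length were chosen after the result was seen, and what other splits of the libraries would show was also written down after it.

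Libraries GX DMSO 1 and GX MRL5 1 came from different treatment groups and were the most alike pair of the 91. Over the 300 genes most variable in the other libraries, their deviations correlated at r = 0.898, against at most 0.734 in any other pair. RNA of 1 animal in both libraries may account for this: the spread in variable genes over that in stable genes was 1.40, above the bound of 1.2 set for it and below all 90 other pairs (lowest 1.78), so it remains open, and 2 simulated redraws of 1 library also exceeded the bound, at 1.28. Libraries made side by side may be another source. The 6 other pairs with adjacent index numbers ran from r = -0.00428 to 0.599. The highest was GX MRL5 4 with WT DMSO 2, which also held atrial Myl7 at 133 and 3967. It came only just within the bound set after the result was seen, so that source stays open too. Nsd2 was at 260 in GX DMSO 1 and 504 in GX MRL5 1, and no biological explanation, such as littermates or a mouse that did not respond, was tested.

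Inflammatory genes were higher by 1.14 on the log2 scale in GX mice with MRL5 than with DMSO (camera adjusted p = 1.46e-13, and adjusted p = 0.432 with an estimated correlation), and their response differed between genotypes by 1.27 (camera adjusted p = 2.77e-05, and adjusted p = 0.849 with an estimated correlation). For the 1.14 in GX mice, a difference between library sets is argued against as the whole source by the median of 0.993 within set 148. The macrophage markers, all 12 measured, had a median of 0.0663, with Lyz2 at 0.06 and C1qa at 0.07, chosen after their values were seen. Its 95% range of 0.0302 to 0.281 came from redrawing these genes and does not measure the spread between mice. Per library, the macrophage mean was higher by 0.142 with MRL5 (exact permutation p = 0.476), and 1 of 5 MRL5 libraries lay above all DMSO libraries. The inflammatory mean was higher by 1.08, with 4 of 5 above, which argues against more macrophages as the whole source. A single library could carry part of the 1.14: without GX MRL5 3 the median in GX mice fell from 1.14 to 0.509, which lay between the bounds set for the test, and the interaction from 1.27 to 0.83. An effect of MRL5 through the GX channel stays open as a hypothesis. Because 4 of the 5 GX MRL5 libraries and not GX MRL5 1 lay above the GX DMSO range, the open question about the alike pair bears on it.

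Ribosomal protein and oxidative phosphorylation genes also differed in response between genotypes, by -0.25 (camera adjusted p = 0.00217) and -0.22 (camera adjusted p = 0.00129), each with an adjusted p = 0.849 with an estimated correlation. A shift between short and long transcripts is a candidate explanation: unlisted genes matched on length and level had medians of 0.136 (WT, MRL5 against DMSO), 0.144 (GX against WT under DMSO) and -0.173 (interaction) beside the ribosomal list, and of 0.113, 0.131 and -0.137 beside the oxidative phosphorylation list. Each of the 6 list medians lay inside the 95% range of its matched genes. Only list members were kept out of the matching, so unlisted genes of the same families could be among the matched genes. A real shift of these families would move such genes too, so the match cannot separate it from a shift by length. Across the 14 libraries the short-transcript index correlated with the ribosomal mean at r = 0.924 (permutation p = 2e-05, rho = 0.846) and, without the 2 farthest libraries, at 0.849, and with the oxidative phosphorylation mean at r = 0.742 (permutation p = 0.0018, rho = 0.644), which fell to 0.489 (permutation p = 0.105) without them. List genes were not left out of the index. Its correlations and the calls lost with it as a covariate therefore cannot separate a shift by length from a real change of these genes. A difference by genotype or compound stays open as well.

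Other lists whose response to MRL5 differed between genotypes by the interaction test were glycolysis (-0.16, adjusted p = 0.0187), circadian clock (0.20, adjusted p = 0.0238) and erythroid genes (0.64, adjusted p = 0.00742). The glycolysis median was 0.00563 with the library set as a covariate. None was called with an estimated correlation (adjusted p = 0.849 for glycolysis, 0.524 for circadian clock and 0.849 for erythroid genes).

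14 values lay far from the rest of their group among 252 tests. This was Dixon's test, run only within GX DMSO and GX MRL5, so no WT library could be flagged. A share of 5% would give 12.6. That number is only a rough guide, since many of the genes were named for a small p in these data and the tests are not independent. In GX DMSO 4 these were Csrp3 at 26643, Rps20 at 1661 and Rps3 at 7976. In GX DMSO 1 they were a low Hspa8 at 9563, Serpina3n at 593 and the glucocorticoid list mean at 9.73, and in GX DMSO 2 Scn4a at 580.1. In GX MRL5 3 they were Ifi205 at 1368, Junb at 1281 and the immediate early list mean at 9.92. In GX MRL5 4 the low values were Rps20 at 882, Sgk1 at 202 and the glucocorticoid list mean at 9.18, and in GX MRL5 1 Rps14 was high at 11631. Genes were tested on log2(value + 1), and their values are given before the log. Hspa1a at 53385 and Atf3 at 6805 in GX MRL5 3 were not flagged on that scale. The number of flags therefore does not rank how far the libraries deviate.

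Other splits of the same libraries were fitted with only the 2 groups compared, which is why the real numbers here can differ from those of all 14 libraries (585 and 802 genes at unadjusted p under 0.05, and 8 lists for GX against WT under DMSO). For MRL5 against DMSO in GX mice, 51 of 100 splits drawn gave as many genes at unadjusted p under 0.05 as the 589 of the real split (highest other 2110), and 80 of 100 as many lists as the 7 of the real split (highest other 18). For GX against WT under DMSO, 7 of 35 gave as many genes as 946 (highest other 1347) and 28 of 35 as many lists as 7 (highest other 16). Chance therefore cannot be excluded for these 4 numbers. The number of genes passing after adjustment was 0 in both real splits, so all 100 and all 35 splits reach it whatever they hold (highest other 2 in each) and it says nothing about chance. The split with 2110 genes, several times the real number, points to a structure of the samples: it had GX DMSO 2, GX DMSO 3, GX MRL5 2, GX MRL5 3 and GX MRL5 4 on 1 side and so kept the alike pair together.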

How the results depend on the processing

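Settings with both alike libraries left out, the short-transcript index as a covariate, and list counts other than those with the set covariate, an estimated correlation, fry or a library left out were chosen after the data were seen. Causes were not tested unless stated. No paired analysis was possible because replicate numbers follow record order. Depth limits genes with low values, and count tests were not run because the unit is not counts.

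Gene counts were 0 in 91 of 101 settings. With a library left out they ran from 0 to 2 for MRL5 against DMSO in GX mice, 0 to 58 in WT mice, 0 to 63 for GX against WT under MRL5 and 0 to 27 for the interaction. They were 0 in each setting for GX against WT under DMSO. Only the groups compared gave 1 gene for GX against WT under MRL5 (the predicted gene Gm20388, chosen after its value was seen). Equal column sums gave 1 gene for the interaction (Nsd2), and the alike pair left out gave 2. Equal column sums gave a median of all genes of -0.11 in GX against WT under DMSO, against -0.02 without them.

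Genes at an unadjusted p under 0.05 moved by over 1.5 times in 16 of 96 settings. In GX mice the number was 1021 without GX MRL5 1 (585 in all). For WT mice (799) it was 430 within set 148, 247 without WT MRL5 1, 2477 without WT MRL5 2 and 418 with the index. For GX against WT under DMSO (802) it was 368 with the set covariate, 411 with set and index series, 333 within set 148 and 436 without WT DMSO 3. Under MRL5 (932) it was 545 and 2112 without WT MRL5 1 and 2. For the interaction (904) it was 516 within set 148, 1379 without GX MRL5 1, 366 and 2301 without WT MRL5 1 and 2, and 482 with the index.

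With an estimated correlation and with fry, 0 lists passed in each comparison, where the preset gave 7, 2, 8, 6 and 6 in the order of the report. With a library left out the list counts ran from 6 to 13, 1 to 8, 4 to 16, 4 to 8 and 2 to 11. In WT mice 5 lists passed with the mean filter, 5 with only the groups compared, 7 with the set covariate, 10 with set and index series and 5 within set 148. For GX against WT under DMSO 4 passed with the set covariate, 1 within set 148, 4 without the alike pair and 5 with the index. Under MRL5 12 passed with equal column sums. For the interaction 13 passed with the set covariate, 14 with set and index series and 10 within set 148.

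Of 626 list values, 472 kept direction and call, 142 lost the call, and in 12 the direction of the camera test turned, none of them called. The medians of these were, with the index, -0.0085 for ribosomal genes in WT mice and -0.0014 in the interaction. For GX against WT under DMSO they were -0.10 and -0.15 for glucocorticoid genes and 0.000902 and -0.29 for immediate early genes, with the set covariate and with set and index series. Within set 148 they were -0.0269 for conduction, -0.0334 for endothelial and -0.0013 for oxidative phosphorylation genes. The interferon median ran from -0.53 to 0.12 over the libraries left out. The glycolysis interaction was 0.00563 with the set covariate and 0.0299 within set 148. Camera tests a list against other genes, so its direction can turn where a median keeps its sign. Of 4186 values of named genes, 3902 moved by less than 1 SE without a new call, 269 moved by more and 15 became called.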

Other observations

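Tests of list means and of the correlation under other settings were chosen after the result was seen.

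p53 target genes, which respond to DNA damage and other stress, had a list mean of 7.25 ± 0.0714 (SD, n = 5) in GX mice with MRL5 and 7.10 ± 0.0746 (SD, n = 4) with DMSO, higher in 5 of 5 libraries than in each DMSO library. The exact permutation p was 0.0159, the smallest possible for these groups, and 0.540 after adjustment over 34 lists, so it did not pass. Mesothelial markers, which line the heart surface, had list means from 1.70 in GX MRL5 3 to 6.38 in GX MRL5 4.

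The correlation across genes of the compound effects in GX and WT mice was -0.119, -0.193 with the library set as a covariate and -0.116 within set 148. Of the 86 genes that the authors marked as cardiac conduction genes, 43 had a positive and 43 a negative fold change in GX mice with MRL5, and none passed when adjusted over the list alone.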
